A study of Homo sapiens with 8 samples.

How the data were processed

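RNA was measured in 8 libraries of HT29, an established human colorectal adenocarcinoma cell line, in 4 groups of 2 libraries: the DMSO vehicle at 0.1%, ICG-001 at 10 µM, CWP232228 at 1.5 µM and YB-0158 at 0.3 µM. Per the labels, total RNA with a quality number of at least 8 went into TruSeq RNA v2 libraries, a kit that does not mark strand, and was sequenced on an Illumina NextSeq instrument. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

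The submitters' processing notes name fastp, Salmon 1.3.0, DESeq2 and the build GRCh38, with no role or order. Per the file headers, each library's deposited file gives Salmon's estimated counts and TPM for every transcript, together with an effective transcript length. The authors' 3 deposited tables give, for each compound against DMSO, a gene's mean signal as normalized counts over libraries, its log2 fold change and its p-value. The same deposited tables hold FPKM per gene and library, which were read for the unit check and used in no test. TPM values were likewise used in no test. The transcriptome release, the way genes were summarised and the authors' filters are not given in the sources used here.

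Estimated counts of the 228754 transcripts were matched by identifier without version to GENCODE release 29 on GRCh38, which gave 204677 matches (89.5%) in 58193 genes. Symbols of 57832 genes came from a table of current gene names. Transcripts with no match took between 1.54% and 1.85% of the estimated reads of a library and entered no test. Of 16407 genes with a mean in the authors' tables, 350 came out below 50% of it, so a named gene among them is given with its share of the authors' mean. Counts were summed per gene and rounded to whole numbers. Salmon divides reads that fit several transcripts by a model, so genes that share reads with a near-identical copy, a readthrough transcript or an overlapping gene are given as uncertain.

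Gene differences were tested in edgeR 4.0.16 under R 4.3.3 with TMM scaling, the low-count filter filterByExpr and the robust quasi-likelihood test. All 8 libraries entered 1 model with 4 groups and 4 residual degrees of freedom, and 16449 genes were tested. The model gives each gene 1 spread for all groups. The SD of the log2 difference between replicates was, however, 0.32 for DMSO and 0.14 to 0.16 for the compounds. P-values against DMSO may thus be too small and their intervals too narrow, while those between compounds may be too large and too wide. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and every adjusted p given for a gene comes from this fit unless another is named. Levels are counts scaled to library size (CPM) with the SD over 2 libraries, and fold changes are on the log2 scale with their SE and, for differences between compounds, their 95% interval. Changes in transcript usage were tested with edgeR's diffSpliceDGE on transcript counts, with a gene's p by the Simes method. Total estimated reads ran from 29071547 to 58489118 per library, and a count of 0, which allows up to 3 counts, set a floor between 0.052 and 0.105 CPM. Counting intervals and floors cover counting error only, and the other 95% intervals come from the fitted model, with the spread between libraries.

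Before the data were examined, 39 gene lists holding 981 distinct genes were fixed for this cell line and these compounds. They cover Wnt/beta-catenin targets, stem cell and differentiation markers, the cell cycle, stress responses, sterol and energy metabolism, the ribosome and proteasome, signalling targets, splicing regulators, and markers of fibroblasts, leukocytes and endothelium. Each was tested with camera in limma 3.58.1, with a preset correlation of 0.01 on log2 CPM (prior count 2), adjusted over the 39 lists and the 3 comparisons of a kind. With a correlation estimated from the residuals, none of these calls held in any of the 6 comparisons, so that p stands beside each list. Members called over all genes tested are given beside those adjusted over the list alone.

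The rule for named genes was fixed at the same time. It takes, for each compound against DMSO, the 5 genes with the largest rise and the 5 with the largest fall among called genes with a mean of at least 2 on the log2 CPM scale, an ordinary symbol and no overlap between the libraries of the 2 groups. It adds the 3 members with the smallest p of the 8 lists with the smallest camera p, and KHDRBS1, CREBBP, CTNNB1, MYC, BIRC5, CD44, LGR5 and PROM1. Between compounds it takes the same 5 and 5 genes and 3 members of 4 lists. For transcript usage it takes 3 genes per compound, with a mean of at least 4 on the log2 CPM scale and a share that moved by at least 10 percentage points. Genes named outside this rule are said to have been chosen after their values were seen.

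Comparisons against DMSO share the same 2 control libraries. Unchanged groups were therefore simulated 20 times against the same controls. A split of the controls would leave 1 library in each part and was not made. The alternatives chosen then were DESeq2 size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, a replicate block, average transcript length offsets, a fit of only the 2 groups compared, a fold change of at least 1 on the log2 scale, an estimated correlation between genes, a stricter transcript filter (50 counts and 10% of the gene), and leaving out each library in turn. Where a library was left out, the remaining one was assumed to vary like the other groups. A correction for GC content and length was added after the fold changes against DMSO were seen to follow GC content. It removes from each library a spline with 5 degrees of freedom on the GC content and length of a gene's main transcript, fitted on genes with at least 5 CPM.

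The gene test was tested on simulated data with the real library sizes. Every library was drawn from the DMSO means, with a spread per gene shared by all groups and no trend with GC content. The cholesterol synthesis list was also lowered for each compound. The real DMSO libraries lay further apart and fold changes followed GC content, so the rates below need not hold for the real data. With 100 genes changed by 1.5-fold and 100 by 2-fold among 15827, the gene test recovered 57.0% and 83.0% for ICG-001 against DMSO, 53.0% and 89.0% for CWP232228, and 56.0% and 83.0% for YB-0158. Of its calls, 11.2%, 12.6% and 8.1% were false, above the nominal 5%. The transcript test, checked on 10860 genes with a fixed spread, recovered 100.0% of 100 swapped genes in the simulation of ICG-001. There were 20 false calls there and 0 in the simulation of CWP232228, where no gene was swapped. The swapped transcripts were chosen to differ clearly in level, so this recovery applies to large changes only. The single results of 2 genes are not reported here.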

Results

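To describe the mRNA response of HT29 colorectal adenocarcinoma cells to 3 small molecules, libraries from cells given ICG-001 (10 µM), CWP232228 (1.5 µM) or YB-0158 (0.3 µM) were compared with libraries from the DMSO vehicle (0.1%), with 2 libraries in each group. The labels give 48 h for 6 libraries and 49 h for replicate 2 of ICG-001 and of CWP232228. ICG-001 is known as a ligand of the transcriptional coactivator CREBBP and, in later work, of the RNA-binding protein KHDRBS1. The 2 DMSO libraries lay further apart than those of any treated group. Over 11014 genes, the SD of the log2 difference between replicates was 0.32 for DMSO, 0.14 for ICG-001, 0.16 for CWP232228 and 0.14 for YB-0158. In each group this difference followed the GC content of the genes, with a Spearman rho across genes of 0.59 for DMSO and of -0.72, -0.54 and -0.52 for the 3 compounds, where genes are not independent replicates.

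With ICG-001, genes of the ATF4 and integrated stress response rose, together with the mRNAs encoded in mitochondria. SLC6A9, a glycine transporter, reached 47.5 ± 2.3 CPM against 1.61 ± 0.168 CPM in DMSO (mean ± SD of 2 libraries each), with a log2 fold change of 4.88 (SE 0.14, adjusted p = 1.0e-06). PSAT1 and ASNS, enzymes of serine and asparagine synthesis, rose by 2.77 and 2.65 on the log2 scale. Genes of cholesterol synthesis, DNA replication, mitosis, glycolysis and the ribosome fell.

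Other genes with a very large rise under ICG-001 included UNC5B, a netrin receptor on chromosome 10 (71212570 to 71302864; log2 fold change 5.37, SE 0.16), and BEST1, a chloride channel on chromosome 11 (4.37, SE 0.19). The long noncoding RNA LINC01133 rose 184-fold over 0.0704 ± 0.0504 CPM in DMSO (95% counting interval 71.5 to 675), with summed reads at 0.62 of the mean in the authors' deposited tables. The readthrough transcript IFNAR2-IL10RB, at 0 in both DMSO libraries, was at least 55.9-fold higher against the floor of 3 counts per library, and shares its sequence with IFNAR2 and IL10RB, so its level is uncertain. Among the genes that fell were FABP1, a fatty acid carrier of enterocytes (1.73 ± 0.0872 against 20 ± 11.5 CPM, -3.53), NDUFA4L2, a hypoxia-responsive mitochondrial protein (4.13 ± 0.437 against 44.1 ± 24.1 CPM, -3.41), the hypoxia-responsive carbonic anhydrase CA9 (-2.79, SE 0.20) and APLP1 (-2.78, SE 0.24), summed to 0.47 of the authors' deposited mean. Without replicate 2 of DMSO, the fall of FABP1 was -2.79 and that of NDUFA4L2 was -2.72, and the fitted log2 fold change of LINC01133 was 8.40 instead of 7.46.

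Of 30 tested members of the ATF4 and integrated stress response list, 28 rose and 0 fell with ICG-001 (28 and 0 adjusted over the list alone), with a median log2 fold change of 1.79 (camera adjusted p = 3.2e-14, and adjusted p = 0.34 with an estimated correlation). FGF21, a member at 0 in DMSO, was at least 6.84-fold higher, and the median stays at 1.79 with it at this bound. Of 20 aminoacyl-tRNA synthetases, 13 rose and 4 fell (13 and 4 adjusted over the list alone). The median was 0.68 (adjusted p = 7.8e-04, and adjusted p = 0.63 with an estimated correlation). GARS1 rose by 1.93 while QARS1, FARSA and VARS1 fell by 0.94, 0.64 and 0.40 on the log2 scale, 4 genes chosen after their values were seen. All 13 mitochondrially encoded mRNAs rose (13 adjusted over the list alone), with MT-ND2, a subunit of respiratory complex I, at 5460 ± 57.9 against 725 ± 201 CPM (2.91, SE 0.18). The median was 1.86 (adjusted p = 2.5e-07, and adjusted p = 0.63 with an estimated correlation). These mRNAs took 4.43% and 4.4% of the estimated reads in the ICG-001 libraries and 0.92% and 1.43% in DMSO. Of 21 NF-kB targets, 8 rose and 1 fell (8 and 1 adjusted over the list alone). The median was 0.44 (adjusted p = 0.028, and adjusted p = 0.63 with an estimated correlation). Without replicate 1 of ICG-001, 5 NF-kB targets were called higher. The call ended without replicate 1 of DMSO (adjusted p = 0.11).

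Cholesterol synthesis genes fell with ICG-001 in 21 of 26 tested members, with 0 higher (21 lower adjusted over the list alone). The median was -0.85 (adjusted p = 1.1e-08, and adjusted p = 0.23 with an estimated correlation). INSIG1, which retains the sterol sensor SCAP, fell by 1.62, and FDPS, farnesyl diphosphate synthase, fell by 1.45 on the log2 scale. In the G1/S and DNA replication list 30 of 42 members fell and 0 rose (30 lower and 1 higher adjusted over the list alone), among them thymidine kinase TK1 (-1.45, SE 0.08), the helicase subunit MCM5 (-1.34) and DNA ligase LIG1 (-1.27). The median was -0.56 (adjusted p = 2.1e-08, and adjusted p = 0.63 with an estimated correlation). In the G2/M and mitosis list 28 of 43 fell and 0 rose (29 and 0 adjusted over the list alone), including the ubiquitin-conjugating enzyme UBE2C (-1.18) and securin PTTG1 (-1.27). The median was -0.69 (adjusted p = 1.0e-07, and adjusted p = 0.63 with an estimated correlation). Replication-dependent histones fell in 9 of 15 (10 adjusted over the list alone). The median was -0.81 (adjusted p = 0.012, and adjusted p = 0.63 with an estimated correlation).

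Cytosolic ribosomal protein genes fell in 48 of 53 with ICG-001 (48 adjusted over the list alone). The median was -0.61 (adjusted p = 6.0e-12, and adjusted p = 0.66 with an estimated correlation), and -0.36 after correction for GC content and length. Nuclear oxidative phosphorylation genes fell in 30 of 38 (31 adjusted over the list alone), opposite to the mRNAs of the mitochondrial genome. The median was -0.38 (adjusted p = 5.3e-08, and adjusted p = 0.63 with an estimated correlation), and -0.25 corrected. In the glycolysis and hypoxia list 22 of 29 fell and 3 rose (22 and 3 adjusted over the list alone). The median was -0.68 (adjusted p = 1.3e-05, and adjusted p = 0.65 with an estimated correlation). Aldolase ALDOC (-2.30) and the lactate exporter SLC16A3 (-1.18) fell, while VEGFA, the angiogenic growth factor, rose from 87 ± 4.83 to 274 ± 6.32 CPM (1.65, SE 0.08). Proteasome genes fell in 18 of 30 and rose in 2 (18 and 3 adjusted over the list alone). The median was -0.27 (adjusted p = 0.023, and adjusted p = 0.82 with an estimated correlation). The call ended without replicate 1 of ICG-001 (adjusted p = 0.083) and after correction for GC content and length (median -0.10, adjusted p = 0.09), and 9 proteasome genes were called lower without either ICG-001 library.

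In all, 8025 of 16449 tested genes changed with ICG-001 (48.8%), 4075 higher and 3950 lower, and 1885 of them by at least 1 on the log2 scale. The fold changes followed GC content (rho = -0.42 across genes), 5584 of the calls remained after correction for it, and without replicate 2 of ICG-001 the count was 5140.

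**Figure D1:**
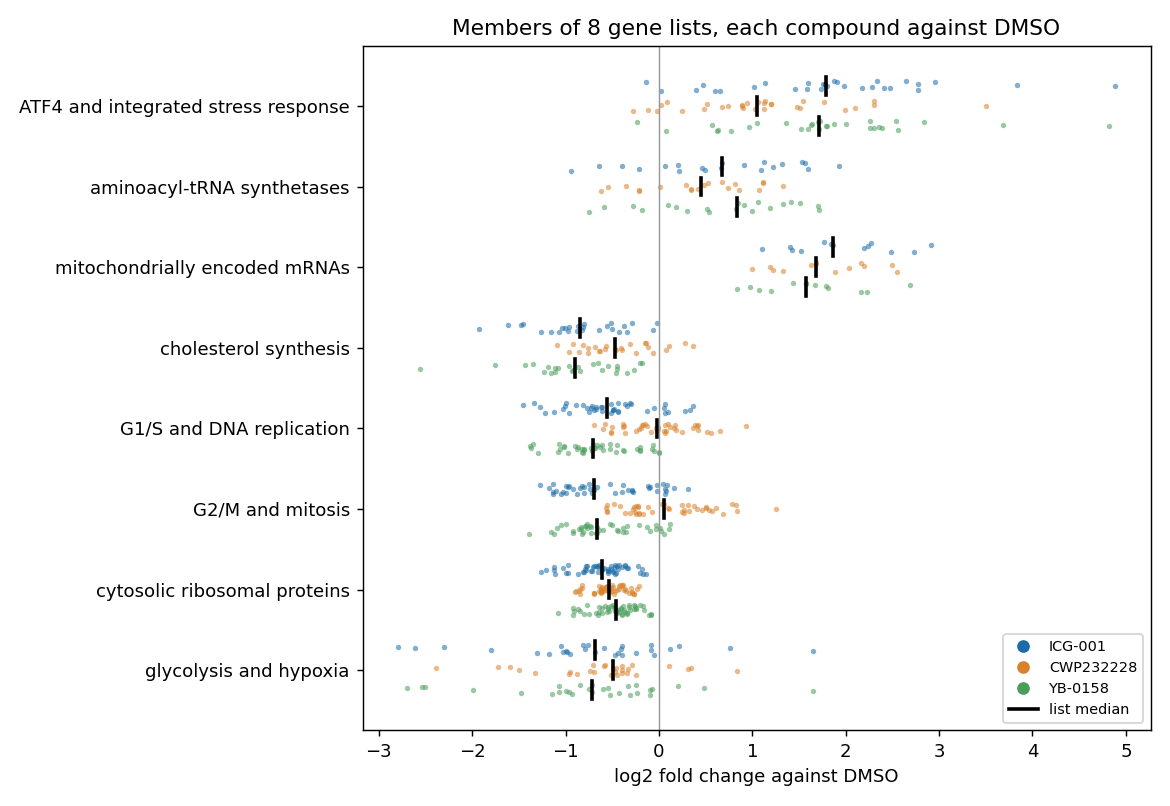
Log2 fold changes against DMSO of the tested members of 8 gene lists for ICG-001, CWP232228 and YB-0158 (2 libraries per group). Each point is 1 gene and each bar the median of a list. FGF21, at 0 in both DMSO libraries, is drawn at its lower bound. Members of the ATF4 list lie mostly above 0 with all 3 compounds, while those of the G1/S and G2/M lists lie mostly below 0 with ICG-001 and YB-0158 and on both sides of 0 with CWP232228.

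With CWP232228, genes of the stress response rose too, and members of the cell cycle lists moved both ways. SLC6A9 reached 18.3 ± 2.26 CPM (log2 fold change 3.50, SE 0.14, adjusted p = 1.6e-05), ASNS 333 ± 16.5 against 67.6 ± 1.75 CPM (2.30) and PSAT1 325 ± 3.72 against 81.7 ± 8.24 CPM (1.99). ULBP1, a ligand of the NKG2D receptor of natural killer cells on chromosome 6 (149964007 to 149973710), rose by 3.40 (SE 0.23). Mitochondrially encoded mRNAs rose, and genes of the ribosome, oxidative phosphorylation, glycolysis and cholesterol synthesis fell.

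ERCC6L2 rose by 4.06 (SE 0.26) under CWP232228, but its summed reads are 0.17 of the authors' deposited mean, and the authors' deposited table gives a log2 fold change of 1.11. LINC01133 rose 59.9-fold (95% counting interval 23.1 to 222), and IFNAR2-IL10RB was at least 38.4-fold higher against the same floor. Lower were NDUFA4L2 (-3.56, SE 0.47), FABP1 (-2.56, adjusted p = 0.0071), the stress-responsive gene NDRG1 (32.3 ± 6.31 against 170 ± 50.4 CPM, -2.39), the monoamine transporter SLC29A4 (-1.82, SE 0.26) and NME1-NME2 (-1.86), a readthrough whose level is uncertain. Without replicate 2 of DMSO, NDUFA4L2 stood at -2.87, FABP1 at -1.83 and LINC01133 at 6.78 (5.84 with it), and without replicate 2 of CWP232228 the adjusted p of FABP1 was 0.056.

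The ATF4 and integrated stress response list had 24 of 30 members higher and 0 lower with CWP232228 (25 and 1 adjusted over the list alone). The median was 1.04, also with FGF21 at its bound of at least 2.3-fold (adjusted p = 1.6e-10, and adjusted p = 0.49 with an estimated correlation). Of 20 aminoacyl-tRNA synthetases 14 rose and 3 fell (14 and 4 adjusted over the list alone), with WARS1 at 207 ± 5.59 against 98.7 ± 1.74 CPM (1.07, SE 0.06), EPRS1 at 1.11 and IARS1 at 1.11 on the log2 scale. The median was 0.45 (adjusted p = 0.0049, and adjusted p = 0.63 with an estimated correlation). That list's call ended without replicate 1 of DMSO (adjusted p = 0.061). All 13 mitochondrially encoded mRNAs rose (13 adjusted over the list alone), to 3.95% and 3.68% of the estimated reads. The median was 1.68 (adjusted p = 9.0e-08, and adjusted p = 0.63 with an estimated correlation). Of them MT-ND4L rose by 2.20 and MT-ATP8 by 2.55.

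Cholesterol synthesis genes fell in 17 of 26 with CWP232228 and rose in 0 (17 lower adjusted over the list alone), including FDPS (-0.92), the sterol reductase TM7SF2 (-0.86) and DHCR7, the last enzyme of the pathway (-0.76). The median was -0.47 (adjusted p = 2.8e-05, and adjusted p = 0.34 with an estimated correlation). Ribosomal protein genes fell in 47 of 53 (49 adjusted over the list alone). The median was -0.53 (adjusted p = 1.4e-12, and adjusted p = 0.66 with an estimated correlation), and -0.26 after correction for GC content and length. Nuclear oxidative phosphorylation genes fell in 25 of 38 (28 lower and 1 higher adjusted over the list alone), with the complex IV subunit COX4I1 at -0.69 and cytochrome CYC1 at -0.71. The median was -0.36 (adjusted p = 1.5e-07, and adjusted p = 0.63 with an estimated correlation), and -0.22 corrected. In the glycolysis and hypoxia list 25 of 29 fell and 2 rose (25 and 3 adjusted over the list alone). The median was -0.49 (adjusted p = 9.8e-07, and adjusted p = 0.63 with an estimated correlation). ALDOC fell by 1.72 and VEGFA rose by 0.84. Proteasome genes fell in 14 of 30 and rose in 3 (16 and 4 adjusted over the list alone). The median was -0.25 (adjusted p = 0.027, and adjusted p = 0.82 with an estimated correlation), and -0.11 corrected. The call ended without replicate 2 of CWP232228 (adjusted p = 0.054). Without replicate 1 or 2 of CWP232228, 29 and 30 ribosomal protein genes and 9 and 4 proteasome genes were called lower, and without replicate 2 also 14 genes each of oxidative phosphorylation and of glycolysis and hypoxia.

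The G1/S list, with 8 members higher and 11 lower with CWP232228 (10 and 11 adjusted over the list alone), was not called (median -0.01, adjusted p = 0.61). Nor was the G2/M list, with 15 higher and 13 lower (15 and 15 adjusted over the list alone), at a median of 0.05 (adjusted p = 0.98). After correction for GC content and length the G2/M list was called lower (median -0.14, adjusted p = 0.0042). Before that correction the proliferation marker MKI67, chosen after its values were seen, rose by 0.69 (adjusted p = 0.0012). It is 1 of the 15 higher members, beside 13 lower, and proliferation itself was not measured. Histones, with 6 of 15 lower (6 adjusted over the list alone), and NF-kB targets, with 3 of 21 higher and 2 lower (1 and 1 adjusted over the list alone), were not called as lists (adjusted p = 0.069 and 0.72).

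In all, 7042 genes changed with CWP232228 (42.8%), 3555 higher and 3487 lower, and 971 by at least 1 on the log2 scale. The fold changes followed GC content (rho = -0.58), 3013 of the calls remained after correction for it, and the count was 4177 without replicate 1 and 2747 without replicate 2 of CWP232228.

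With YB-0158, at 0.3 µM, genes of the stress response rose, and genes of the cell cycle and of cholesterol synthesis fell. SLC6A9 reached 45.6 ± 0.813 CPM (log2 fold change 4.82, SE 0.14, adjusted p = 1.9e-06), PSAT1 rose by 2.56 and ASNS by 2.54. FABP1 fell to 0.726 ± 0.376 CPM (-4.72, SE 0.53), and RASL11A, a small GTPase on chromosome 13 (27270327 to 27273690), from 46.5 ± 6.43 to 7.25 ± 0.626 CPM (-2.68, SE 0.12). UNC5B (24.8 ± 0.571 against 0.772 ± 0.208 CPM) and BEST1 (4.35) rose, and NDUFA4L2 (-3.55) and NDRG1 (-2.70) fell. LINC01133 was 169-fold higher (95% counting interval 65.8 to 621) and IFNAR2-IL10RB at least 67.4-fold higher against the same floor. FABP1 stood at -3.98 without replicate 2 of DMSO and at -5.43 without replicate 1 of YB-0158, and NDUFA4L2 at -2.85 and LINC01133 at 8.27 (7.33 with it) without replicate 2 of DMSO.

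The ATF4 and integrated stress response list had 28 of 30 members higher and 1 lower with YB-0158 (28 and 1 adjusted over the list alone). The median was 1.72, also with FGF21 at its bound of at least 3.99-fold (adjusted p = 3.6e-15, and adjusted p = 0.34 with an estimated correlation). The member that fell was ATF5 (-0.23). Of 20 aminoacyl-tRNA synthetases 14 rose and 3 fell (15 and 4 adjusted over the list alone). The median was 0.84 (adjusted p = 1.6e-04, and adjusted p = 0.63 with an estimated correlation). All 13 mitochondrially encoded mRNAs rose (13 adjusted over the list alone), to 3.5% and 3.56% of the estimated reads. The median was 1.58 (adjusted p = 6.9e-07, and adjusted p = 0.63 with an estimated correlation). NF-kB targets rose in 10 of 21 and fell in 1 (12 and 1 adjusted over the list alone). The median was 0.45 (adjusted p = 0.012, and adjusted p = 0.63 with an estimated correlation). The call ended without replicate 1 of DMSO (adjusted p = 0.058), and 5 members were called higher without replicate 1 of YB-0158. BIRC3, an inhibitor of apoptosis, rose by 1.99 and the cytokine LTB fell by 2.32, both chosen after their values were seen. YAP/TEAD targets rose in 10 of 17 and fell in 1 (10 and 1 adjusted over the list alone). The median was 0.39 (adjusted p = 0.027, and adjusted p = 0.66 with an estimated correlation). Without either YB-0158 library, 6 YAP/TEAD targets were called higher.

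Cholesterol synthesis genes fell in 21 of 26 with YB-0158 and rose in 0 (22 lower adjusted over the list alone), with INSIG1 at -1.75, FDPS at -1.35 and DHCR7 at -1.15. The median was -0.89 (adjusted p = 6.7e-10, and adjusted p = 0.23 with an estimated correlation). Fatty acid synthesis genes fell in 7 of 14 and rose in 1 (9 and 1 adjusted over the list alone). The median was -0.33 (adjusted p = 0.009, and adjusted p = 0.5 with an estimated correlation), and -0.61 after correction for GC content and length. In the G1/S list 31 of 42 fell and 0 rose (34 and 0 adjusted over the list alone). The median was -0.70 (adjusted p = 7.0e-12, and adjusted p = 0.63 with an estimated correlation). In the G2/M list 32 of 43 fell and 0 rose (32 and 0 adjusted over the list alone). The median was -0.66 (adjusted p = 3.7e-09, and adjusted p = 0.63 with an estimated correlation). TK1 fell by 1.38, LIG1 by 1.37, MCM5 by 1.35 and the spindle protein gene NUSAP1 by 1.12. Histones fell in 9 of 15 (10 adjusted over the list alone). The median was -0.76 (adjusted p = 0.0017, and adjusted p = 0.5 with an estimated correlation).

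Ribosomal protein genes fell in 40 of 53 with YB-0158 (43 adjusted over the list alone). The median was -0.46 (adjusted p = 1.1e-09, and adjusted p = 0.71 with an estimated correlation), and -0.24 after correction for GC content and length. Nuclear oxidative phosphorylation genes fell in 27 of 38 (28 adjusted over the list alone). The median was -0.37 (adjusted p = 6.6e-08, and adjusted p = 0.63 with an estimated correlation), and -0.28 corrected. In the glycolysis and hypoxia list 23 of 29 fell and 3 rose (23 and 3 adjusted over the list alone). The median was -0.72 (adjusted p = 1.4e-06, and adjusted p = 0.63 with an estimated correlation). Lactate dehydrogenase LDHA fell by 1.07 and ALDOC by 2.50, while VEGFA rose by 1.65. Proteasome genes fell in 16 of 30 and rose in 0 (17 and 1 adjusted over the list alone). The median was -0.24 (adjusted p = 0.01, and adjusted p = 0.82 with an estimated correlation). The call ended after correction for GC content and length (median -0.12, adjusted p = 0.084). Without either YB-0158 library 5 proteasome genes were called lower, and without replicate 2 of YB-0158 22 ribosomal protein genes.

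In all, 7209 genes changed with YB-0158 (43.8%), 3575 higher and 3634 lower, and 1577 by at least 1 on the log2 scale. The fold changes followed GC content (rho = -0.38), 5206 of the calls remained after correction for it, and the count was 4436 without replicate 1 and 4237 without replicate 2 of YB-0158.

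**Figure D2:**
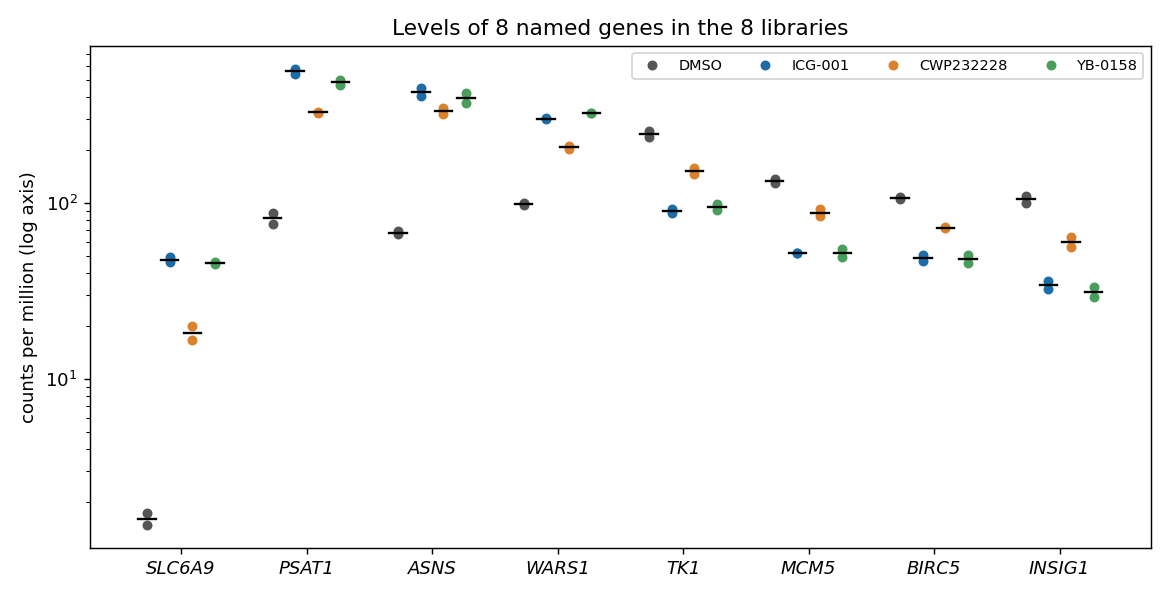
Levels of 8 genes in the 8 libraries, as CPM on a log axis, with bars at the mean of the 2 libraries of each group. SLC6A9, PSAT1, ASNS and WARS1 are higher, and INSIG1 lower, in every treated library than in both DMSO libraries. TK1, MCM5 and BIRC5 are lowest in the ICG-001 and YB-0158 libraries.

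KHDRBS1 mRNA, at 231 ± 21.3 CPM in DMSO, was not called with any compound. The log2 fold changes were -0.11 (95% interval -0.30 to 0.08) with ICG-001, 0.04 (-0.15 to 0.24) with CWP232228 and -0.04 (-0.23 to 0.15) with YB-0158. It was called lower with ICG-001 without replicate 2 of DMSO (-0.22, adjusted p = 0.032) and after correction for GC content and length (-0.20, adjusted p = 0.018). CREBBP rose by 0.68, 0.45 and 0.84 with ICG-001, CWP232228 and YB-0158, a call that ended for CWP232228 without replicate 1 (adjusted p = 0.077) or replicate 2 (adjusted p = 0.053) of that compound. BIRC5, which encodes the mitotic protein survivin, fell by 1.13, 0.56 and 1.15.

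CTNNB1, which encodes beta-catenin, rose by 0.19 with ICG-001 (adjusted p = 0.048) and by 0.24 with YB-0158 (adjusted p = 0.021), and stood at 0.14 with CWP232228 (adjusted p = 0.13). The CTNNB1 calls ended without replicate 2 of DMSO (adjusted p = 0.16 and 0.052), without replicate 1 or 2 of ICG-001 (0.091 and 0.21) or of YB-0158 (0.1 and 0.12), and after correction for GC content and length (0.79 and 0.1). They ended as well with average transcript length offsets (log2 fold change 0.03 and 0.10, adjusted p = 0.76 and 0.35) and in a fit of only the 2 groups (0.17 and 0.07), and with ICG-001 under DESeq2 size factors (0.067) and the DESeq2 Wald test (0.063). Without replicate 1 of DMSO, CTNNB1 was called with CWP232228 too (0.21, adjusted p = 0.016). MYC, with summed reads at 0.83 of the authors' deposited mean, fell by 0.43, 0.36 and 0.32 with ICG-001, CWP232228 and YB-0158. The MYC calls ended without replicate 2 of ICG-001 (adjusted p = 0.053), without replicate 2 of CWP232228 (0.13) and without either YB-0158 library (0.1 each), and after that correction with CWP232228 and YB-0158 (0.077 and 0.051).

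Of the stem cell markers in the rule, PROM1 rose by 0.40, 0.50 and 0.41 with ICG-001, CWP232228 and YB-0158. No PROM1 call remained after correction for GC content and length (adjusted p = 0.41, 0.12 and 0.11) or with average transcript length offsets (0.24, 0.48 and 0.16), and the calls also ended without replicate 2 of ICG-001 (0.07) and replicate 2 of YB-0158 (0.061). CD44 was not called at -0.05, 0.02 and -0.18, but was lower after that correction (-0.39, -0.31 and -0.49) and with YB-0158 without replicate 2 of DMSO (-0.24, adjusted p = 0.015) or by the DESeq2 Wald test (-0.19, adjusted p = 0.025). LGR5 fell with YB-0158 by 0.57 (adjusted p = 0.0076, against 0.062 without replicate 2 of YB-0158 and 0.22 with average transcript length offsets, at -0.33) and was not called with ICG-001 at -0.31 or CWP232228 at 0.05. Without replicate 2 of DMSO it was lower with ICG-001 (-0.42, adjusted p = 0.034), and after the correction with ICG-001 and CWP232228 (-0.68 and -0.33).

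Targets of Wnt/beta-catenin signalling moved both ways. Of 23 tested, 5 rose and 7 fell with ICG-001, 4 rose and 5 fell with CWP232228, and 5 rose and 5 fell with YB-0158. The counts adjusted over the list alone were the same (camera adjusted p = 0.38, 0.78 and 0.93). The list medians were -0.08, 0.02 and -0.03. After correction for GC content and length they were -0.31, -0.16 and -0.09, and the list was still not called (camera adjusted p = 0.1, 0.26 and 0.56). NOTUM, a secreted Wnt deacylase, fell by 2.33, 1.88 and 2.30, SP5 by 1.46, 1.04 and 1.26 and ASCL2 by 1.18, 0.70 and 0.88. AXIN2, a negative regulator of the pathway, rose by 0.79, 0.54 and 0.88 and PROX1 by 1.10, 1.01 and 1.24. These 5 genes were chosen after their values were seen. Colorectal stem cell markers (adjusted p = 0.3, 0.13 and 0.48), markers of enterocytes and colonocytes (0.56, 0.56 and 0.54), goblet and secretory cells (0.33, 0.74 and 0.71) and enteroendocrine cells (0.3, 0.61 and 0.5) were not called as lists, in the order ICG-001, CWP232228 and YB-0158. Markers of fibroblasts, of which 3 were tested (adjusted p = 0.84, 0.98 and 0.9), leukocytes, with 4 tested (0.15, 0.37 and 0.23), and endothelium, with 4 tested (0.93, 1 and 0.66), were not called either.

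Stress lists that were not called, in the same order of compounds, were p53 targets (adjusted p = 0.98, 0.88 and 0.93), apoptosis regulators (0.7, 0.99 and 0.78), ER chaperones and the unfolded protein response (0.83, 0.92 and 0.66) and cytosolic heat shock genes (0.93, 0.72 and 1). NRF2 targets (adjusted p = 0.12, 0.72 and 0.18), metallothioneins (0.24, 0.34 and 0.17) and the interferon response (0.84, 0.61 and 0.98) were not called. NRF2 targets were called higher after correction for GC content and length with ICG-001 (median 0.36, adjusted p = 0.0084) and YB-0158 (0.31, adjusted p = 0.013). Nor were signalling lists, namely EMT and TGF-beta targets (0.3, 0.18 and 0.13), ERK feedback targets (0.3, 0.48 and 0.22) and immediate early genes (0.27, 0.069 and 0.61), although ERK feedback targets were called higher with YB-0158 after that correction (median 0.22, adjusted p = 0.049). Fatty acid oxidation and PPAR targets were not called (adjusted p = 0.13, 0.22 and 0.099), but were called lower with each compound after the correction (medians -0.33, -0.26 and -0.28, adjusted p = 0.017, 0.0052 and 0.013). Also not called were nucleolar ribosome biogenesis (0.66, 0.38 and 0.67), epithelial junctions and keratins (0.75, 0.93 and 0.38), and lysosome and autophagy genes (0.74, 0.27 and 0.72). Xenobiotic metabolism (adjusted p = 0.17, 0.37 and 0.47), SR proteins, hnRNPs and splicing regulators (0.92, 0.27 and 0.98) and partners of KHDRBS1 and CREBBP (0.98, 0.98 and 0.93) were not called. Single members did change. Of 37 splicing genes 12 rose and 11 fell with ICG-001 (13 and 14 adjusted over the list alone), 16 and 3 with CWP232228 (16 and 3 adjusted over the list alone), and 11 and 12 with YB-0158 (14 and 14 adjusted over the list alone). Fatty acid synthesis was not called with ICG-001 (adjusted p = 0.054) or CWP232228 (0.27), but was called lower with both after correction for GC content and length (medians -0.53 and -0.31, adjusted p = 0.0089 and 0.0065). YAP/TEAD targets were not called with either (0.13 and 0.27).

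Cells given CWP232228 at 1.5 µM had higher cell cycle mRNAs and lower stress response mRNAs than cells given ICG-001 at 10 µM. Of 43 tested G2/M genes 36 were higher and 0 lower (42 and 0 adjusted over the list alone). The median was 0.65 (adjusted p = 5.2e-27, and adjusted p = 0.31 with an estimated correlation). Of 42 G1/S genes 29 were higher and 0 lower (39 and 0 adjusted over the list alone). The median was 0.60 (adjusted p = 4.1e-24, and adjusted p = 0.31 with an estimated correlation). BUB1, a spindle checkpoint kinase, differed by 0.95, thymidylate synthase TYMS by 0.74 and LIG1 by 0.78 on the log2 scale, and BUB1 and LIG1 missed the threshold with average transcript length offsets (adjusted p = 0.058 and 0.062). Of 30 ATF4 and integrated stress response genes 24 were lower (26 lower and 1 higher adjusted over the list alone), with CHAC1, a glutathione-degrading enzyme, at 29 ± 5.05 against 84.2 ± 6.09 CPM (-1.54, SE 0.12) and SLC6A9 at -1.38. The median was -0.79 (adjusted p = 9.1e-20, and adjusted p = 0.31 with an estimated correlation). Without replicate 1 or 2 of CWP232228 or replicate 1 or 2 of ICG-001, 17, 7, 5 and 34 of the 85 cell cycle genes were called higher and 12, 7, 9 and 14 of the stress response genes lower.

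CSPG4, a membrane proteoglycan on chromosome 15, was higher with CWP232228 than with ICG-001 (112 ± 0.65 against 38.2 ± 0.815 CPM, 1.55, SE 0.08). APLP1, summed to 0.47 of the authors' deposited mean, was higher by 2.50. UNC5B (-2.10, SE 0.12), CLGN, an ER chaperone (-2.04, SE 0.17), and LINC01133 (-1.62) were lower, as were PRSS2 (-2.09) and PRSS1 (-1.60), near-identical trypsinogens whose reads cannot be assigned with certainty. Cholesterol synthesis genes were higher in 10 of 26 (17 adjusted over the list alone). The median was 0.33 (adjusted p = 5.6e-09, and adjusted p = 0.21 with an estimated correlation). CTSV (1.22) and CA9 (1.21) were higher, but CTSV missed the threshold without replicate 2 of CWP232228 (adjusted p = 0.052) and CA9 without any 1 of the 4 libraries (between 0.08 and 0.15). SR proteins, hnRNPs and splicing regulators were higher in 4 of 37 (11 adjusted over the list alone). The median was 0.12 (adjusted p = 0.0067, and adjusted p = 0.64 with an estimated correlation). Fatty acid synthesis genes were higher in 2 of 14 and lower in 1 (6 and 1 adjusted over the list alone). The median was 0.25 (adjusted p = 0.028, and adjusted p = 0.35 with an estimated correlation). Without replicate 1 or 2 of CWP232228 or replicate 1 or 2 of ICG-001, 1, 0, 0 and 2 cholesterol synthesis genes and 0, 0, 0 and 1 fatty acid synthesis genes were called higher, and 0 splicing regulators each time. The splicing call ended without replicate 1 of ICG-001 (0.067) or replicate 2 of CWP232228 (0.075), and the fatty acid call without replicate 2 of ICG-001 (0.051) or replicate 1 of CWP232228 (0.096).

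NRF2 targets were lower with CWP232228 than with ICG-001 in 10 of 26 (13 adjusted over the list alone). The median was -0.35 (adjusted p = 8.3e-06, and adjusted p = 0.44 with an estimated correlation). Aminoacyl-tRNA synthetases were lower in 9 of 20 (10 lower and 1 higher adjusted over the list alone). The median was -0.28 (adjusted p = 2.4e-04, and adjusted p = 0.35 with an estimated correlation). NF-kB targets were lower in 3 of 21 (3 adjusted over the list alone). The median was -0.30 (adjusted p = 0.0014, and adjusted p = 0.35 with an estimated correlation). Lysosome and autophagy genes were lower in 4 of 29 (6 adjusted over the list alone). The median was -0.12 (adjusted p = 0.0012, and adjusted p = 0.35 with an estimated correlation). With any 1 of the 4 libraries left out, the members called lower were 0 NRF2 targets, at most 2 synthetases, and at most 1 each of the NF-kB and lysosome lists. In all, 1121 genes differed, 600 higher and 521 lower with CWP232228, and 133 by at least 1 on the log2 scale. The doses differ, so compound and dose cannot be separated here. The count was 56 without replicate 1 and 259 without replicate 2 of ICG-001, 136 without replicate 1 and 41 without replicate 2 of CWP232228, and 3190 after correction for GC content and length.

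Between YB-0158 at 0.3 µM and ICG-001 at 10 µM, a single gene differed: TXNIP, a thioredoxin-binding regulator of glucose uptake on chromosome 1 (145992435 to 145996600), at 273 ± 3.14 against 150 ± 13.9 CPM (log2 difference 0.87, 95% interval 0.69 to 1.04, adjusted p = 0.036). Against DMSO, TXNIP rose by 0.52 with YB-0158 and fell by 0.34 with ICG-001. Ribosomal protein genes lay higher with YB-0158 as a list (median 0.15, adjusted p = 4.0e-09, and adjusted p = 0.64 with an estimated correlation), and mitochondrially encoded mRNAs lower (median -0.33, adjusted p = 5.6e-06, and adjusted p = 0.58 with an estimated correlation), with 0 members of either called over all genes, and 0 ribosomal protein genes and 2 mitochondrial mRNAs adjusted over the list alone. MT-ND4L stood at -0.45 (-0.64 to -0.27) and RPL28 at 0.30 (0.08 to 0.52), and neither was called. MT-ND4L was called with no filter on low counts (adjusted p = 7.7e-05), in a fit of only the 2 groups (0.037) and by the DESeq2 Wald test (0.002).

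ER chaperones (median 0.12, adjusted p = 5.7e-05, and adjusted p = 0.31 with an estimated correlation) also lay higher with YB-0158 than with ICG-001, with 0 members called over all genes and 3 adjusted over the list alone. So did Wnt/beta-catenin targets (0.10, adjusted p = 0.0013, and adjusted p = 0.35 with an estimated correlation) and immediate early genes (0.10, adjusted p = 0.012, and adjusted p = 0.58 with an estimated correlation), with 0 members by either count. The chaperone HSPA5 stood at 0.29 (95% interval 0.13 to 0.45; adjusted p = 0.66, and 0.036 by the DESeq2 Wald test). G1/S genes lay lower (-0.10, adjusted p = 1.6e-05, and adjusted p = 0.58 with an estimated correlation). Fatty acid synthesis genes (-0.07, adjusted p = 0.025, and adjusted p = 0.35 with an estimated correlation) and xenobiotic metabolism genes (-0.06, adjusted p = 0.025, and adjusted p = 0.35 with an estimated correlation) lay lower too. Of these lists 0 members were called over all genes, and 0, 1 and 2 members adjusted over the list alone. The G1/S call ended without replicate 1 of YB-0158 (adjusted p = 0.15) and the xenobiotic call without replicate 1 of ICG-001 (0.19). The fatty acid call ended without replicate 1 (0.091) or 2 (0.057) of ICG-001 or replicate 2 of YB-0158 (0.2), and with no filter on low counts (0.19). The immediate early call ended without replicate 2 of ICG-001 (0.16) or replicate 1 of YB-0158 (0.3), with no filter (0.061), and after correction for GC content and length (0.11).

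The single call between YB-0158 and ICG-001 by edgeR stands beside 918 genes at an unadjusted p under 0.05, where chance alone would give about 822, and 27 genes called by the DESeq2 Wald test. It does not show that the compounds act alike, and the libraries of these groups were also the deepest. The 95% interval of the difference lay within 1 on the log2 scale in both directions for 13446 genes (81.7%), with a median width to either side of 0.29. The count was 0 without replicate 1 of ICG-001, 1 without its replicate 2, 0 without replicate 1 of YB-0158 and 2 without its replicate 2, and TXNIP lost its call without any 1 of these libraries (adjusted p = 0.4, 0.074, 0.25 and 0.17) and with average transcript length offsets (0.16).

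Cells given YB-0158 at 0.3 µM had lower cell cycle and higher stress response mRNAs than cells given CWP232228 at 1.5 µM. G1/S genes were lower in 36 of 42 (40 adjusted over the list alone). The median was -0.69 (adjusted p = 7.2e-28, and adjusted p = 0.31 with an estimated correlation). G2/M genes were lower in 38 of 43 (43 adjusted over the list alone), with the kinetochore gene SPC25 at -1.22, TYMS at -0.85 and the ribonucleotide reductase subunit RRM1 at -0.80. The median was -0.61 (adjusted p = 1.7e-26, and adjusted p = 0.31 with an estimated correlation). Stress response genes were higher in 23 of 30 (24 higher and 1 lower adjusted over the list alone). The median was 0.68 (adjusted p = 4.2e-17, and adjusted p = 0.31 with an estimated correlation). Without replicate 1 or 2 of CWP232228 or replicate 1 or 2 of YB-0158, 30, 14, 10 and 48 of the 85 cell cycle genes were called lower and 13, 9, 10 and 15 of the stress response genes higher. TRIB3, a pseudokinase induced under stress, stood at 425 ± 7.37 against 166 ± 21.4 CPM (1.35, adjusted p = 0.001). CLGN (2.09), UNC5B (1.73) and ITPKA, an inositol phosphate kinase (11.4 ± 0.924 against 3.76 ± 0.0178 CPM, 1.60), were higher. The alcohol dehydrogenase ADH6 (-1.53) and RASL11A (-1.44) were lower.

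Cholesterol synthesis genes were lower with YB-0158 than with CWP232228 in 11 of 26 (19 adjusted over the list alone). The median was -0.39 (adjusted p = 1.7e-09, and adjusted p = 0.21 with an estimated correlation). Fatty acid synthesis genes were lower in 3 of 14 (8 adjusted over the list alone). The median was -0.30 (adjusted p = 4.6e-04, and adjusted p = 0.31 with an estimated correlation). Histones were lower in 2 of 15 (2 adjusted over the list alone). The median was -0.32 (adjusted p = 0.019, and adjusted p = 0.35 with an estimated correlation). Aminoacyl-tRNA synthetases were higher in 9 of 20 (11 adjusted over the list alone). The median was 0.32 (adjusted p = 7.1e-05, and adjusted p = 0.35 with an estimated correlation). NRF2 targets were higher in 7 of 26 (9 adjusted over the list alone). The median was 0.26 (adjusted p = 3.5e-04, and adjusted p = 0.56 with an estimated correlation). Lysosome and autophagy genes were higher in 3 of 29 (4 adjusted over the list alone). The median was 0.18 (adjusted p = 0.0039, and adjusted p = 0.35 with an estimated correlation). Without replicate 1 or 2 of CWP232228 or replicate 1 or 2 of YB-0158, 3, 0, 1 and 3 cholesterol synthesis genes and 1, 0, 0 and 1 fatty acid synthesis genes were called lower. With any 1 of these libraries left out, 0 histones and 0 NRF2 targets were called, at most 2 synthetases and at most 2 lysosome genes.

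The remaining lists called between YB-0158 and CWP232228 each lost the call when 1 library was left out, and their called members then fell to at most 2 NF-kB targets, 3 junction and keratin genes, 0 YAP/TEAD targets and 0 splicing regulators. NF-kB targets were higher in 3 of 21 (3 adjusted over the list alone). The median was 0.34 (adjusted p = 0.002, and adjusted p = 0.35 with an estimated correlation) and the call was lost without replicate 1 of CWP232228 (0.063). Epithelial junctions and keratins were higher in 4 of 31 and lower in 1 (5 and 1 adjusted over the list alone). The median was 0.13 (adjusted p = 0.012, and adjusted p = 0.35 with an estimated correlation) and the call was lost without replicate 2 of CWP232228 (0.054). YAP/TEAD targets were higher in 3 of 17 (4 adjusted over the list alone). The median was 0.16 (adjusted p = 0.048, and adjusted p = 0.64 with an estimated correlation) and the call was lost without any 1 of the 4 libraries (0.096 and 0.066 for CWP232228, 0.05 and 0.081 for YB-0158) and after correction for GC content and length (0.057). Splicing regulators were lower in 2 of 37 (3 adjusted over the list alone). The median was -0.11 (adjusted p = 0.019, and adjusted p = 0.64 with an estimated correlation) and the call was lost without replicate 2 of CWP232228 (0.11) or replicate 1 of YB-0158 (0.056), and after that correction (0.053).

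In all, 1279 genes differed, 586 higher and 693 lower with YB-0158, and 148 by at least 1 on the log2 scale. As with the other pairs, the doses differ. The count was 225 without replicate 1 and 92 without replicate 2 of CWP232228, 88 without replicate 1 and 334 without replicate 2 of YB-0158, and 3118 after correction for GC content and length.

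The responses to the 3 compounds resembled one another more than simulated unchanged groups did. Across 16449 genes, the log2 fold changes against DMSO of ICG-001 and YB-0158 correlated at r = 0.87, against 0.54 on average and 0.63 at most in simulated unchanged groups with the same controls. It was 0.79 for ICG-001 and CWP232228 (simulated 0.52 and 0.57) and 0.76 for CWP232228 and YB-0158 (simulated 0.52 and 0.59). In all, 2416 genes were higher and 2553 lower with each of the 3 compounds, and 9, 2 and 35 genes were called in opposite directions by ICG-001 and CWP232228, by ICG-001 and YB-0158, and by CWP232228 and YB-0158. After correction for GC content and length, r was 0.85 for ICG-001 and YB-0158, 0.75 for ICG-001 and CWP232228 and 0.74 for CWP232228 and YB-0158. The simulated groups held no trend with GC content and no systematic difference of the DMSO libraries. The same 2 DMSO libraries enter each comparison and no split of them was made, so how much of the excess comes from the shared controls cannot be told. Over the 9857 genes called against DMSO with at least 1 compound, the principal axis slope was 0.79 for CWP232228 on ICG-001 and 0.95 for YB-0158 on ICG-001. These genes were selected on the same fold changes and both axes share the 2 DMSO libraries, so the slopes do not measure strength of response alone.

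The share of single transcripts within a gene changed for 438 of 11611 tested genes with ICG-001, 398 with CWP232228 and 366 with YB-0158, of which 204 changed with all 3. In BAG6, which encodes a chaperone of newly made proteins, usage changed with ICG-001, CWP232228 and YB-0158 (adjusted p of the gene = 1.4e-13, 2.6e-13 and 3.6e-14). These p-values cover all tested transcripts of the gene, while each transcript named here is the one whose share moved most. BAG6-234 held 44.7 ± 2.9% of the gene's reads in DMSO, 24.1 ± 4.5% with ICG-001 and 30.3 ± 7.5% with CWP232228. BAG6-235 went from 0.0% to 19.1 ± 9.5% with YB-0158. In KTN1, which encodes the kinesin receptor kinectin, KTN1-203 went from 0.0% in DMSO to 22.4 ± 4.2%, 19.2 ± 3.0% and 17.3 ± 2.1% with ICG-001, CWP232228 and YB-0158. In CD276, an immune checkpoint molecule, CD276-202 went from 40.3 ± 1.7% in DMSO to 0.0% with CWP232228 and with YB-0158, and in TMC6 the transcript TMC6-202 from 12.1 ± 4.0% to 0.0% with ICG-001. The shares rest on Salmon's division of shared reads, whose error was not analysed here. All 3 comparisons use the same 2 DMSO libraries. At a common depth of 30 M reads, 267 transcripts were at 0 in DMSO alone, with at least 20 reads in every other library. By that rule 23 were at 0 in ICG-001 alone, 71 in CWP232228 and 24 in YB-0158. Conversely, 79 transcripts reached 20 reads in DMSO alone and were at 0 in every other library. This number was 41 for ICG-001, 47 for CWP232228 and 57 for YB-0158. A share of 0.0% in DMSO, or a change shared by all 3 compounds, can thus not be told apart from a trait of these DMSO libraries. A fall from DMSO to 0.0%, as for CD276-202 and TMC6-202, may likewise reflect these DMSO libraries. With transcripts of at least 50 counts and 10% of their gene, 110, 115 and 107 genes changed and TMC6 was not called (adjusted p = 1). Without replicate 1 of DMSO the counts were 708, 678 and 745. They were 207 and 215 without replicate 1 and 2 of ICG-001, 240 without replicate 1 of CWP232228, and 174 without either YB-0158 library.

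The authors' deposited tables, at an adjusted p under 0.05, hold 2987 genes higher and 3025 lower with ICG-001, 2336 and 2303 with CWP232228, and 2812 and 2778 with YB-0158. Across 16407 genes present in both, their log2 fold changes correlated with those given here at r = 0.73, 0.62 and 0.71. Of 5388, 4092 and 4841 genes called in both, 5379, 4081 and 4834 had the same sign. Their fold changes followed GC content too (rho = -0.41, -0.53 and -0.40).

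**Figure D3:**
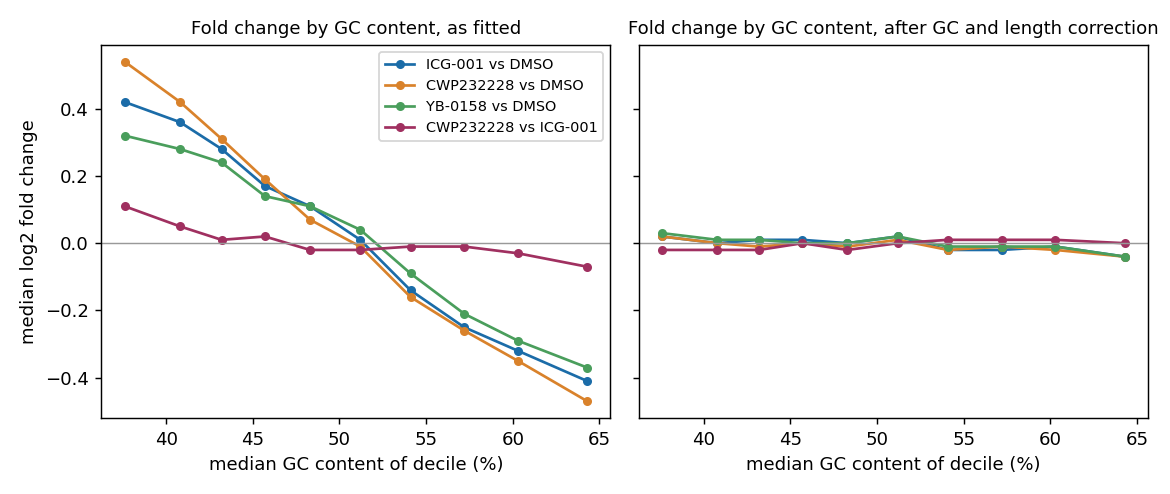
Median log2 fold change of genes grouped in 10 equal classes by the GC content of their main transcript, before and after correction for GC content and length, for the 3 comparisons against DMSO and for CWP232228 against ICG-001. Against DMSO the medians fall from the class of lowest to the class of highest GC content, and they lie near 0 in each class after correction.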

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

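The correction for GC content and length was chosen after the fold changes were seen, and the other alternatives before. With DESeq2 size factors all 6 counts of changed genes stayed within 1.5 times, and for the 3 comparisons against DMSO so they did with no filter on low counts, with a replicate block and with the DESeq2 Wald test. In the following values the cause was not tested, except that a larger fold change admits fewer genes. Requiring a log2 fold change of at least 1 left 1885 genes for ICG-001, 971 for CWP232228 and 1577 for YB-0158 against DMSO, 133 between CWP232228 and ICG-001, 148 between YB-0158 and CWP232228, and 0 between YB-0158 and ICG-001. For CWP232228 against DMSO the count was 3368 with average transcript length offsets, 4646 with the correction for GC content and length and 4144 in a fit of only the 2 groups. Between CWP232228 and ICG-001 it was 2126 with no filter, 653 with a replicate block, 185 with the offsets, 3190 with the correction and 2840 with only the 2 groups. Between YB-0158 and CWP232228 the same settings gave 2378, 814, 229, 3118 and 3293. Between YB-0158 and ICG-001 edgeR gave 268 with no filter, 0 with a replicate block, 0 with the offsets, 16 with the correction and 34 with only the 2 groups, against 918 genes at an unadjusted p under 0.05 (about 822 by chance), and the DESeq2 Wald test gave 27. The replicate block assumes that replicate numbers pair libraries across groups. The deviations of replicate 1 from replicate 2 correlated across genes at -0.28, -0.29 and -0.24 between DMSO and ICG-001, CWP232228 and YB-0158, and at 0.29 between ICG-001 and CWP232228, 0.42 between ICG-001 and YB-0158 and 0.20 between CWP232228 and YB-0158. The numbers were not used as pairs, since the correlation was not positive for all 6, but a shared factor among the treated libraries is not excluded. TXNIP between YB-0158 and ICG-001 stood at 0.87 with the block (adjusted p = 0.28) and CTNNB1 with ICG-001 at 0.19 (adjusted p = 0.068), and the block changed no other call of a list or of the genes chosen by rule. With an estimated correlation between genes, 0 lists were called in any of the 6 comparisons. The correlation of responses with no filter was 0.61 for ICG-001 and CWP232228, 0.68 for ICG-001 and YB-0158 and 0.61 for CWP232228 and YB-0158. Transcripts of at least 50 counts and 10% of their gene gave 110, 115 and 107 genes of changed usage for ICG-001, CWP232228 and YB-0158.

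With 1 library left out, the remaining one was assumed to vary like the other groups. The counts of changed genes then ran from 5140 to 9412 for ICG-001, 2747 to 8798 for CWP232228 and 4237 to 8846 for YB-0158 against DMSO, from 41 to 259 between CWP232228 and ICG-001, 0 to 2 between YB-0158 and ICG-001 and 88 to 334 between YB-0158 and CWP232228. The lists called ran from 11 to 14, 7 to 9, 13 to 15, 9 to 10, 6 to 10 and 11 to 13 in the same order. The correlation of responses ran from 0.66 to 0.85 for ICG-001 and CWP232228, 0.75 to 0.89 for ICG-001 and YB-0158 and 0.66 to 0.84 for CWP232228 and YB-0158. Genes of changed usage ran from 207 to 708, 240 to 678 and 174 to 745, with the highest counts without replicate 1 of DMSO. Of 306 alternatives for the 34 list calls against DMSO, 265 kept the call and 41 lost it, 34 of these with an estimated correlation. Between compounds 224 of 279 kept it. Of 1331 alternatives for named genes against DMSO, 1275 kept direction and side of the threshold, 36 lost and 9 gained a call, and 11 turned direction. Between compounds 577 of 627 kept both, 37 lost and 13 gained a call. The 11 that turned concern genes not called. KHDRBS1 with CWP232228 stood at -0.06 with the correction and between -0.06 (without replicate 2 of DMSO) and 0.15 with 1 library left out, and with YB-0158 at 0.04 with the offsets and between -0.14 and 0.06 (without replicate 1 of DMSO). CTNNB1 with CWP232228 stood at -0.03 with the offsets and -0.05 with the correction. CD44 with CWP232228 stood at -0.31 with the correction and between -0.04 (without replicate 2 of DMSO) and 0.07. LGR5 with CWP232228 stood at -0.33 with the correction and between -0.07 (without replicate 2 of DMSO) and 0.16, and at -0.01 without replicate 1 of CWP232228. The cause was not tested. Depth limits genes at 0 in DMSO, whose level there is known only to lie under 0.105 CPM.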

Other observations

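The genes in the first paragraph, apart from IFNAR2-IL10RB, and the tests in the paragraphs after it were chosen after the results were seen, while the estimated correlation and the fits without 1 library were chosen before. AREG, a ligand of the EGF receptor, rose by 0.96, 0.69 and 1.08 on the log2 scale with ICG-001, CWP232228 and YB-0158, and the cystine transporter SLC7A11 by 2.47, 2.10 and 2.39. The lipogenic enzyme SCD fell by 1.09, 0.51 and 1.21. In both DMSO libraries 5 genes had 0 reads while every treated library had at least 20 at a common depth of 30 M reads, and for each compound group the number of such genes was 0. They were IFNAR2-IL10RB, the pseudogenes EIF4EP2, SLC2A3P1 and SPTLC1P1, and ENSG00000285000, and EIF4EP2 had 19 ± 1.02, 18 ± 7.74 and 14.2 ± 6.94 CPM with ICG-001, CWP232228 and YB-0158. The reads of a pseudogene or a readthrough transcript can belong to the genes it shares sequence with, so these levels are uncertain. By the same rule 267 transcripts were at 0 in DMSO alone, 23 in ICG-001, 71 in CWP232228 and 24 in YB-0158.

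The G1/S and G2/M lists were lower with ICG-001 and YB-0158 against DMSO. A trend with GC content and length is argued against as the whole cause, since the 4 calls kept their direction after it was removed, with adjusted p of at most 1.4e-10, although before the correction none of them held with an estimated correlation between genes (adjusted p = 0.63 each). A difference of the DMSO libraries alone would leave the compounds alike. By comparisons that DMSO does not enter, it is argued against as the whole cause of the differences among the groups. Such comparisons cannot show where a compound lies against an unaltered control. Of the 85 tested members, 65 were higher with CWP232228 than with ICG-001, and 74 were lower with YB-0158 than with CWP232228. These counts fell to between 5 and 34, and between 10 and 48, with 1 of the compared libraries left out, but the median difference of the 85 members then stayed at 0.59 or more in size, against at most 0.13 between the means of 2 libraries of 1 compound. A lower level of cell cycle mRNAs in cells given ICG-001 at 10 µM or YB-0158 at 0.3 µM than in those given CWP232228 at 1.5 µM may thus be biological, as a hypothesis found and tested on the same libraries. Whether dose or compound makes it stays open, as the doses differ. Whether ICG-001 and YB-0158 lie below an unaltered control, or CWP232228 above it, cannot be told, since only the same DMSO libraries serve as controls.

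The ATF4 list rose and the cholesterol synthesis list fell with all 3 compounds. The trend with GC content and length is argued against as the whole cause, since all 6 calls kept their direction after it was removed (adjusted p of at most 1.4e-10), although before the correction none of them held with an estimated correlation (adjusted p from 0.23 to 0.49). A difference of the DMSO libraries alone is argued against as the whole cause, since both lists changed more with ICG-001 and YB-0158 than with CWP232228, by list medians of at least 0.32 in size with any 1 of the compared libraries left out, against at most 0.09 between the means of 2 libraries of 1 compound, while the called members of the cholesterol list fell from 10 and 11 to between 0 and 3. Comparisons between compounds cannot show where a compound lies against an unaltered control, and a part of the greater depth of the ICG-001 and YB-0158 libraries was not tested. For the part of the change that the 3 compounds share, a difference of the DMSO libraries cannot be told apart from a response. Every comparison that shows this part uses the same 2 DMSO libraries. Leaving out 1 of them left the median of the ATF4 list with CWP232228 at 1.00 or more, so no single DMSO library carries it.

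Mitochondrially encoded mRNAs were higher with all 3 compounds. The trend with GC content and length is argued against as the whole cause, since the 3 calls kept their direction after it was removed (adjusted p of at most 9.2e-07), although before the correction none of them held with an estimated correlation (adjusted p = 0.63 each). A higher yield of all mitochondrial RNA would raise the rRNA MT-RNR1 about as much only if the libraries capture rRNA and mRNA alike, which was not tested. The log2 change of MT-RNR1 was -0.38, -0.60 and -0.42 with ICG-001, CWP232228 and YB-0158, with upper 95% bounds of at most 0.09. It was called lower with CWP232228 (adjusted p = 0.047). MT-RNR2 stood at 0.64, 0.33 and 0.18, and was called higher with ICG-001 (95% interval 0.21 to 1.07, adjusted p = 0.024). The smallest change of an mRNA was 1.10, 1.00 and 0.84. Both rRNAs thus changed by less than the mRNAs, but without a known capture of rRNA a higher mitochondrial yield is not excluded. DMSO does not enter the difference between YB-0158 and ICG-001 (medians of -0.33 or lower with at most 1 of their libraries left out, against 0.06 and 0.04 between the 2 libraries of ICG-001 and of YB-0158, but 0.17 in CWP232228 and 0.56 in DMSO), but for the rise shared by the 3 compounds, with at least 3.50% of reads on these mRNAs in a treated library against 0.92% and 1.43% in DMSO, a difference of the DMSO libraries alone cannot be told apart from a response, since no other control library was analysed here.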
